A study of Homo sapiens with 60 samples.

How the data were processed

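RNA from MDA-MB-231 cells was measured in 60 libraries of 16 groups, 6 DMSO libraries at each of 1, 3, 6 and 24 h and 3 libraries for each of 100, 300 and 1000 nM BAY2506856 at each time. Libraries were stranded and poly(A) selected, and were sequenced as single reads. Per the submitters' processing notes, reads were aligned with STAR 2.4.2a to hg19, counted with featureCounts 1.4.6-p2 of the Subread package and tested with DESeq2. The annotation release is not given in the sources used here. The deposited table holds log2 values of FPKM (fragments per kilobase of transcript per M reads) plus 1 for 38342 gene names in the 60 libraries. FPKM had been assumed when the tests were fixed, so each deposited log2 value was converted back to FPKM (2 to the power of the value, minus 1).

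Whole read numbers were recovered from the FPKM by finding, for each gene and library, the steps in which the values occur. All 1304094 values above 0 lay within 0.01 read of a whole number (100%). On simulated values the reads of 99.94% of 3257 genes were recovered. The recovered depth was 0.475 to 86.5 M reads per library, with a median of 11.2 M. DMSO libraries had 7.48 to 30.8 M reads at 1 h, 2.37 to 48.6 at 3 h, 4.80 to 24.0 at 6 h and 0.475 to 12.95 at 24 h. The 1000 nM libraries had 3.69 to 7.37, 1.45 to 12.2, 7.80 to 13.6 and 2.27 to 31.8 M at these times. The 300 nM libraries had 5.61 to 13.4, 8.55 to 12.9, 7.34 to 12.9 and 1.89 to 86.5 M, and the 100 nM libraries had 3.22 to 12.3, 8.08 to 13.1, 9.31 to 48.8 and 9.52 to 14.4 M. The 3 libraries under 2 M reads were 300 nM 24 h replicate 2, 1000 nM 3 h replicate 2 and DMSO 24 h replicate 2. Reads carry no molecular identifiers, so depth does not give the number of separate RNA molecules counted.

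Of 36114 genes above 0 in any library, the 15866 with at least 1 FPKM in at least 3 libraries were tested. The package limma 3.58.1 in R 4.3.3 was fitted to log2(FPKM + 0.5) with 1 mean per group over all 60 libraries and 44 residual degrees of freedom, with a mean-variance trend and robust variances. Genes with a Benjamini-Hochberg adjusted p under 0.05 within a comparison were called changed. The 20 comparisons were each dose against DMSO of the same time (12), 1000 nM against 100 nM at each time (4), the change of the 1000 nM effect between successive times (3), and DMSO at 24 h against 1 h. Overlaps between times were counted only across times, which have separate DMSO libraries. Group levels are means with SD of FPKM, and log2 changes carry limma's standard error.

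The gene lists numbered 27 and were fixed before the data were examined. They cover YAP1/TAZ targets, SRF/MRTF and actin genes, prenylation enzymes, the mevalonate pathway, S phase, mitosis, cell cycle inhibitors and p53 targets, immediate early genes, KLF factors, NF-kB targets, interferon-stimulated genes, the unfolded protein response, NRF2 and aryl hydrocarbon receptor targets, glycolysis and hypoxia, extracellular matrix, the BCL2 family, lysosome and autophagy, ribosome biogenesis and the respiratory chain. The others hold markers of 5 cell types and 2 sets of RNA quality. The results of 1 list and of some single genes are not reported here. The 24 lists with at least 5 tested members were tested with camera (limma) at a preset correlation of 0.01 in the 12 comparisons with DMSO, a total of 288 tests, with Benjamini-Hochberg adjustment over the 24 lists within each comparison. Each of these set tests over all libraries was repeated with an estimated correlation. The set tests in the other settings described below used the preset correlation only.

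Genes were named by a rule fixed beforehand. It took the 6 highest and 6 lowest log2 changes at 1000 nM at each time among changed genes whose libraries did not overlap with DMSO, up to 4 members of each list with the largest change at 24 h, 11 genes always named, and the 3 highest and 3 lowest of each other comparison. The rule excluded XIST, Y-linked genes and names without a symbol. Genes named outside it are marked as such.

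The alternatives fixed beforehand were a pseudocount of 0.1, no filter on low values, median-of-ratios scaling, array weights, only the groups compared, an estimated correlation in set tests, and leaving out each library in turn. Further alternatives were chosen after the data had been seen: terms for the library types, the first library type only, without the third type, without the libraries under 2 M reads, voom on the recovered reads, each library's trend with GC content taken out, GC trends and type terms together, and array weights with type terms. The library types were found in the values, from the mean log2(FPKM + 0.5) of 6 pseudogenes minus that of 5 others and from MT-ND6. GC content came from GENCODE 29 transcripts on GRCh38 by gene symbol, for 13279 of the 15866 genes (83.7%). Because this build differs from the hg19 of the deposited values, no coordinates are given. Of the tested names, 13569 were found as current or older symbols.

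The tests were checked on simulated values with the real depths of the 60 libraries, in which 200 of 15866 genes changed at 1000 nM after 24 h. With limma, 55.2% of 67 genes changed 1.5-fold, 79.1% of 67 changed 2-fold and 98.5% of 66 changed 4-fold were recovered. Of 197 calls, 42 (21.3%) were genes without a change, against 6 of 168 (3.6%) at equal depths. On reads, voom had 13 of 169 (7.7%). The camera test of limma returned 2.06e-15 for a set of 40 genes lowered to 0.8-fold and 0.756 for a set of 40 unchanged genes, as unadjusted p-values. These genes were drawn independently, so the check does not bear on the preset correlation. No pair of replicates held the same library: over 96 pairs with genes of at least 20 reads, chi-square per degree of freedom was 1.53 to 124.6, with a median of 7.68. Other computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Isoforms, variants and fusion transcripts were not analysed here.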

Results

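MDA-MB-231 cells, an established triple-negative breast cancer line, were treated with DMSO or with 100, 300 or 1000 nM of BAY2506856 for 1, 3, 6 or 24 h. The times are those of the sample labels, while the text on the design of the series gives a harvest at 24 h only. Poly(A) RNA from 60 libraries was sequenced, 6 DMSO libraries and 3 libraries of each dose at every time. Nothing in the labels says that replicates were separate cultures, so the p-values measure only the spread between these samples. The labels give no target for the compound. The gene lists were fixed before the data were examined for a compound thought to act on the YAP1/TAZ pathway, a transcriptional program that controls growth and adhesion genes. Of 15866 genes tested with limma, the number past a Benjamini-Hochberg adjusted p of 0.05 at 1000 nM was 0 at 1 h, 21 at 3 h, 319 at 6 h and 5506 at 24 h.

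**Figure D1:**
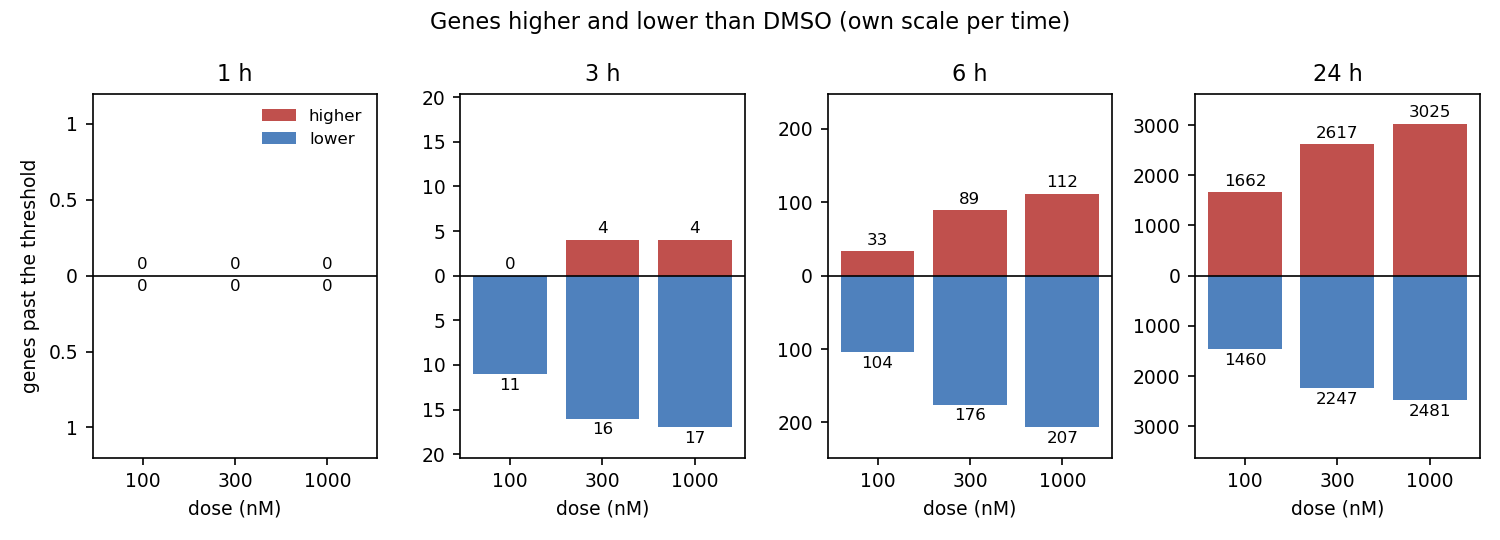
Number of genes higher (bars above 0) and lower (bars below 0) than in DMSO by dose, in a panel for each time with its own vertical scale, from limma with a Benjamini-Hochberg adjusted p under 0.05. At 24 h the totals were 3122 genes at 100 nM, 4864 at 300 nM and 5506 at 1000 nM, and at 1 h all 3 doses had 0.

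The libraries fell into 3 types that the labels do not describe. The types were told apart by an index of 11 pseudogenes and by the mitochondrial message MT-ND6. The first type held 41 libraries. The second held 13 libraries from all 4 times, with an index of 2.82 to 5.62 against -0.84 to 0.03 in the first. The third held 3 DMSO libraries at 1 h and 3 DMSO libraries at 3 h, in which MT-ND6 measured 56.9 to 105 FPKM against 0.85 to 5.71 FPKM in the first type. Values within the first type, and with a model term for each of the other two, are given beside the pooled counts. The first type leaves a single 1000 nM library at 1 h and at 24 h, which is then assumed to vary like the other groups.

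**Figure D2:**
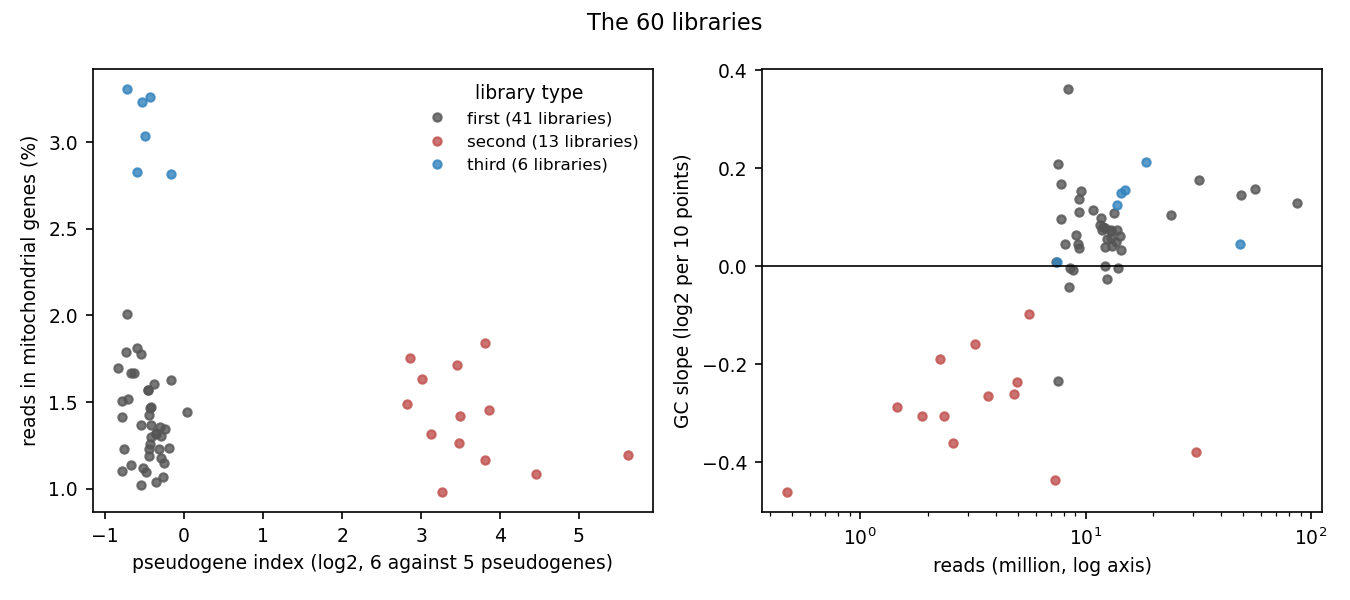
Each point is 1 of the 60 libraries, marked by library type: the share of reads in mitochondrial genes (%) against the pseudogene index (log2, left), and the slope of expression on GC content (log2 per 10 points) against the number of reads (M, log axis, right). The 13 libraries of the second type lie at an index of 2.82 or more, and the 6 of the third type at 2.82 to 3.31% mitochondrial reads.

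After 1 h the YAP1/TAZ targets CYR61 (CCN1) and CTGF (CCN2), which encode secreted matricellular proteins, were at their DMSO level. At 1000 nM the log2 change was -0.13 ± 0.07 (SE) for CYR61 and 0.00 ± 0.07 for CTGF, with adjusted p values of 0.479 and 0.983. RHOB, a growth factor-inducible gene, was not past the threshold either at -0.34 ± 0.18 (adjusted p = 0.479). All 22 YAP1/TAZ targets missed the threshold at 1000 nM, with a median of 0.07. The 13 mitochondrially encoded messages had medians of -0.57, -0.46 and -0.42 at 1000, 300 and 100 nM (adjusted p = 8.95e-05, 6.19e-09 and 0.00257). At 1 h 3 of the 6 DMSO libraries were of the third type, and with type terms the direction of this list turned upward at all 3 doses. With an estimated correlation the adjusted p values of this list were 0.595, 0.308 and 0.556. The 37 nuclear respiratory chain genes also passed downward at 1000 nM (median -0.13, adjusted p = 0.00045, and 0.595 with an estimated correlation), with 0 members past the threshold, and stayed lower with type terms (adjusted p = 1.54e-07). The test with limma called 0 genes at each dose, with 1637, 192 and 809 genes at an unadjusted p under 0.05 for 1000, 300 and 100 nM. On the recovered reads voom also called 0 at each dose, and the library type terms gave 0, 0 and 1.

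After 3 h the first genes past the threshold were mostly lower and included YAP1/TAZ targets. CYR61 fell by 1.19 ± 0.07 (SE) on the log2 scale at 1000 nM, from 224 ± 11.5 FPKM (SD, n = 6) to 97.9 ± 2.09 FPKM (SD, n = 3), with an adjusted p of 7.96e-17. CTGF fell by 0.83 ± 0.07 (adjusted p = 1.68e-12), and AMOTL2, which encodes an angiomotin that binds YAP1, fell by 1.01 ± 0.18 (adjusted p = 0.0011). CD274, which encodes the immune checkpoint ligand PD-L1, fell by 0.73, and EDN1, which encodes the peptide endothelin-1, fell by 0.71 (adjusted p = 8.52e-05 and 0.000587; -0.73 and 0.051 for EDN1 within the first type). The pseudogene NCLP1 fell by 0.74 (adjusted p = 0.0239), but within the first library type its change was -0.43 with an adjusted p of 0.377. Higher were FAM46C, which encodes a poly(A) polymerase, and the antiproliferative gene BTG1, each at 0.48, and the leucine zipper gene TSC22D1 at 0.22 (adjusted p = 0.00407, 0.00123 and 0.00654). Within the first type FAM46C was at 0.47 (adjusted p = 0.0385), BTG1 at 0.33 (0.137) and TSC22D1 at 0.22 (0.0823). Without 1000 nM replicate 2, the library with the fewest reads in this group, the adjusted p was 0.205 for AMOTL2, 0.194 for FAM46C, 0.42 for BTG1 and 0.177 for TSC22D1. The last of the 4 higher genes, RP11-1072A3.4, at 1.33 (adjusted p = 0.0377), was named after its values were seen, and within the first type it was at 1.16 (adjusted p = 0.433).

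Of the 22 YAP1/TAZ targets tested, 5 were lower and 0 higher at 1000 nM after 3 h, and 6 were lower when adjusted over the list alone. The list passed the set test with a median of -0.12 (adjusted p = 1.65e-10, and 0.000643 with an estimated correlation). At 300 nM 4 targets were lower, and at 100 nM 4 were lower, with medians of -0.14 and -0.18. CYR61 fell by 1.07 at 300 nM and by 0.92 at 100 nM. Of the immediate early genes, which respond within minutes to growth factors, 1 was lower and the list median was -0.16 (adjusted p = 0.495 with an estimated correlation). The NF-kB list (median -0.21) and the NRF2 and aryl hydrocarbon receptor list (median 0.07) also passed with the preset correlation only, with adjusted p = 0.309 and 0.0905 with an estimated correlation. The mitochondrially encoded messages had a median of -0.77 and 0 members past the threshold. With library type terms these 4 lists lost their calls (adjusted p = 0.341, 0.182, 0.341 and 0.947), and of the 7 lists that passed only the YAP1/TAZ targets kept call and direction, as was the case within the first type. In total limma called 21 genes at 1000 nM (4 higher and 17 lower), 20 at 300 nM (4 and 16) and 11 at 100 nM (0 and 11). Within the first library type the counts were 28, 25 and 6, of which 13, 15 and 5 were among the pooled calls. Array weights raised the counts to 1978, 2549 and 3413, and with library type terms added they were 46, 43 and 32.

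After 6 h RHOB was the gene with the largest increase and CYR61 the gene with the largest decrease among those past the threshold. RHOB rose by 2.14 ± 0.18 (SE) on the log2 scale at 1000 nM, from 5.94 ± 1.74 FPKM (SD, n = 6) to 27.1 ± 2.53 FPKM (SD, n = 3), with an adjusted p of 2.18e-12. BMF, which encodes a BH3-only activator of apoptosis, rose by 1.25, and the glucocorticoid-induced gene TSC22D3 rose by 1.11. The epithelial transcription factor gene ELF3, the mTORC1 inhibitor gene DDIT4 and the atypical cyclin gene CCNG2 rose by 1.07, 0.98 and 0.89. CYR61 fell by 2.28 ± 0.07, from 279 ± 21.6 to 56.8 ± 1.89 FPKM, and CTGF fell by 2.09 ± 0.07, each with an adjusted p of 3.36e-29. ANKRD1, which encodes a nuclear ankyrin repeat protein, fell by 1.95, EDN1 by 1.71, the WNT antagonist gene DKK1 by 1.70 and AMOTL2 by 1.39.

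Of the 22 YAP1/TAZ targets, 10 were lower and 0 higher at 1000 nM after 6 h, and 12 were lower when adjusted over the list alone. The median was -0.38 (adjusted p = 8.3e-49, and 8.43e-12 with an estimated correlation), and it was -0.47 at 300 nM and -0.34 at 100 nM. Of the 12 KLF transcription factor genes, 6 were higher and 0 lower, with 7 higher and 1 lower when adjusted over the list alone and a median of 0.33 (adjusted p = 2.54e-09, and 7.22e-07 with an estimated correlation). KLF9 rose by 0.51 and KLF7 by 0.59, and KLF2, which encodes an endothelial quiescence factor, rose by 1.21 (adjusted p = 0.0461). KLF2 lost its call within the first library type (1.04, adjusted p = 0.055), without any 1 of the 3 treated libraries (adjusted p = 0.217, 0.148 and 0.208) and without any 1 of DMSO replicates 2, 3, 5 and 6 (0.0711, 0.152, 0.14 and 0.129). Of the 30 ribosome biogenesis and MYC target genes, 9 were lower and 0 higher, with 13 lower when adjusted over the list alone and a median of -0.25 (adjusted p = 2e-18, and 1.06e-11 with an estimated correlation). RRS1 and NOLC1, which encode assembly factors of the nucleolus, fell by 0.88 and 0.38. Of the 21 NRF2 and aryl hydrocarbon receptor targets, 4 were higher and 0 lower, including CYP1B1 at 0.68 and AKR1C2 at 0.45, which encode a cytochrome P450 and a ketosteroid reductase.

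Of the 40 DNA replication and S phase genes, 0 were past the threshold at 6 h and the median was -0.04 (adjusted p = 0.126). The mitosis and G2/M list was called higher with type terms (adjusted p = 0.00127), within the first library type (0.0018) and with GC trends and type terms (0.00156). In the same settings the immediate early genes were called lower (0.00632, 0.0104 and 0.0262). These settings were run with the preset correlation only, and neither list passed over all libraries without these changes. The interferon-stimulated list (median 0.09, with 0 members past the threshold) passed with an adjusted p of 0.0196 with an estimated correlation. In total limma called 319 genes at 1000 nM (112 higher and 207 lower), 265 at 300 nM (89 and 176) and 137 at 100 nM (33 and 104), and 20, 17 and 6 of them changed at least 2-fold. Within the first library type the counts were 1222, 767 and 535, and 318, 253 and 135 of the pooled calls were kept. With library type terms they were 738, 742 and 345. Of the 17 genes lower at 3 h, 16 were lower at 6 h, against 0.222 expected if the calls were independent, and 3 of the 4 higher genes were higher at both times.

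**Figure D3:**
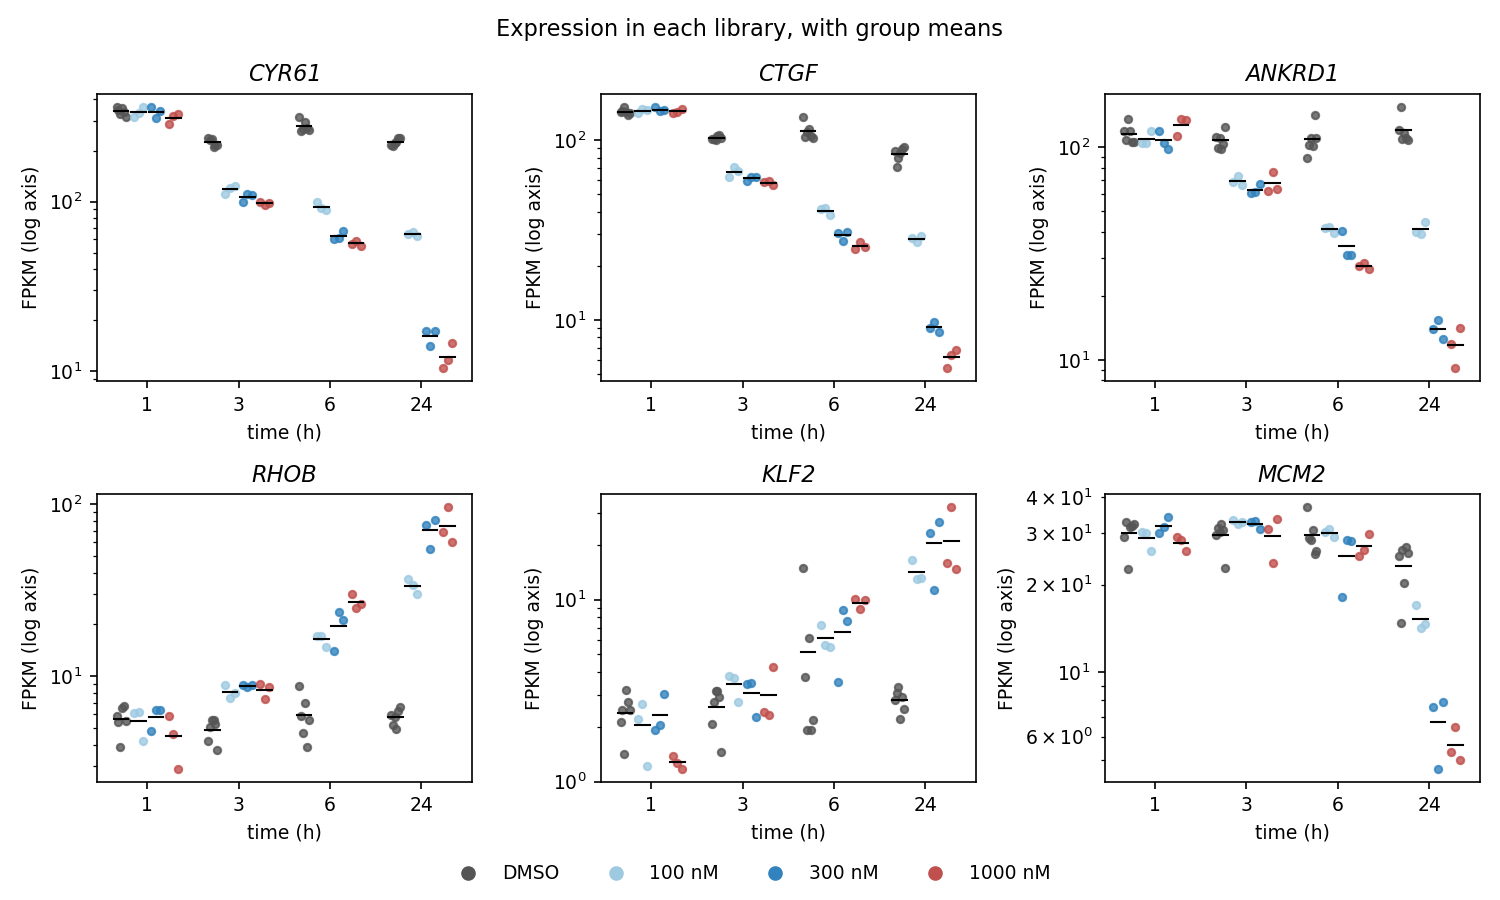
FPKM (log axis) of CYR61, CTGF, ANKRD1, RHOB, KLF2 and MCM2 in each of the 60 libraries by time and dose, with group means as black lines. MCM2, an S phase gene, is outside the rule for named genes. CYR61 lay at 12.2 FPKM on average at 1000 nM after 24 h against 224 FPKM in DMSO, and RHOB at 74.9 against 5.78 FPKM.

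After 24 h RHOB and CYR61 had the highest and the lowest log2 change among the genes past the threshold at 1000 nM, as at 6 h. RHOB rose by 3.56 ± 0.18 (SE) on the log2 scale, an 11.8-fold increase from 5.78 ± 0.632 FPKM (SD, n = 6) to 74.9 ± 18.8 FPKM (SD, n = 3), with an adjusted p of 1.93e-21. NOX5, which encodes a calcium-activated NADPH oxidase, rose by 3.39, PI16, which encodes a peptidase inhibitor, by 2.79, and AGR2, which encodes a disulfide isomerase of secretory cells, by 2.71. KLF2 rose by 2.61 ± 0.34 (adjusted p = 2.02e-08) and the amino acid transporter gene SLC43A2 by 2.4. CYR61 was 17.8-fold lower (log2 change -4.15 ± 0.07, adjusted p = 9.15e-41), at 12.2 ± 2.17 FPKM against 224 ± 10.2 FPKM in DMSO, and CTGF was 12.6-fold lower (adjusted p = 3.28e-40). DKK1 was 10.5-fold lower, ANKRD1 9.96-fold lower and FST, which encodes the activin antagonist follistatin, 8.08-fold lower. The ribosomal protein pseudogene RPL35P4 was at -2.55 (adjusted p = 0.0205) over all libraries and at -0.39 (adjusted p = 0.528) within the first library type.

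The growth-related lists were lower almost throughout at 24 h. All 40 DNA replication and S phase genes were lower at 1000 nM, also when adjusted over the list alone, with a median of -1.45 (adjusted p = 3.46e-56, and 3.21e-21 with an estimated correlation). PRIM1, which encodes the catalytic subunit of primase, fell by 2.34, the origin licensing gene CDC6 by 2.17, UHRF1, which encodes a maintenance methylation factor, by 2.07 and the cyclin gene CCNE2 by 2.01. At 300 nM 40 of the 40 were lower (median -1.27), and at 100 nM 32 were lower and 33 when adjusted over the list alone (median -0.68). Of the 42 mitosis and G2/M genes, 36 were lower and 0 higher, with 37 lower when adjusted over the list alone and a median of -0.65 (adjusted p = 1.36e-20, and 0.00252 with an estimated correlation). The mitotic kinase gene AURKB fell by 1.37 and the anaphase activator gene CDC20 by 1.09, and the proliferation marker MKI67 fell by 0.73 (adjusted p = 1.38e-05). All 30 ribosome biogenesis and MYC target genes were lower, also when adjusted over the list alone (median -0.88, adjusted p = 8.87e-22, and 7.07e-13 with an estimated correlation). RRS1 fell by 1.62, the spermidine synthase gene SRM by 1.46 and BOP1, which encodes a ribosome assembly factor, by 1.41.

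**Figure D4:**
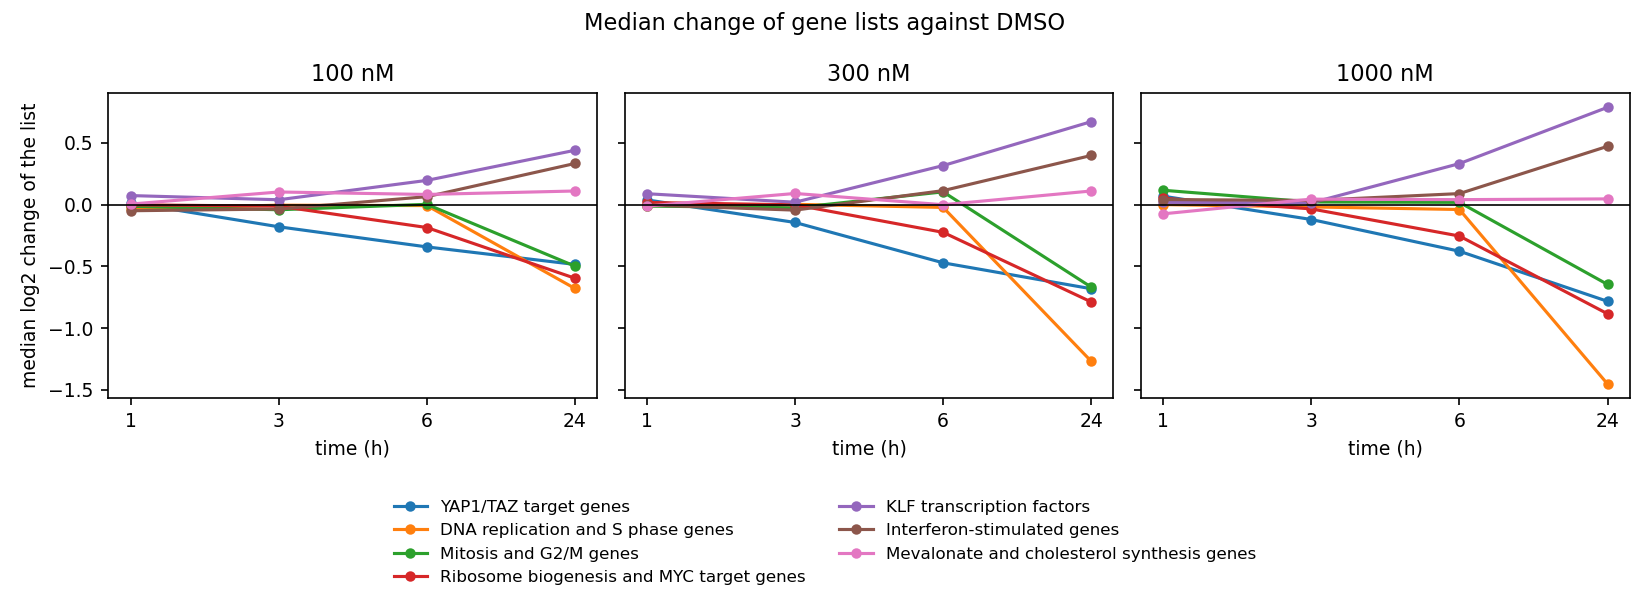
Median log2 change against DMSO of 7 of the fixed gene lists by time (h, equally spaced), in a panel for each dose, with 1 point per list and time. The S phase list lay at -0.04 at 6 h and at -1.45 at 24 h with 1000 nM, while the YAP1/TAZ targets lay at -0.12 at 3 h, -0.38 at 6 h and -0.78 at 24 h.

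Of the 22 YAP1/TAZ targets, 15 were lower and 1 higher at 24 h, also when adjusted over the list alone, with a median of -0.78 (adjusted p = 3.5e-15, and 1.31e-05 with an estimated correlation). Besides CYR61, CTGF and ANKRD1, FJX1, which encodes a secreted growth regulator, fell by 2.07. Of the 27 SRF/MRTF and actin cytoskeleton genes, 10 were lower and 2 higher. Among them were CNN2 (calponin) at -1.0, MYL9 (a myosin light chain) at -0.94 and SRF itself at -0.90. The list did not pass the set test (adjusted p = 0.0583). It passed downward with median-of-ratios scaling (0.0463), without the libraries under 2 M reads (0.0409) and with GC trends and type terms together (0.00516). At 6 h the list had passed downward with the preset correlation, but not with an estimated one (adjusted p = 0.346). Of the 11 protein prenylation enzyme genes 2 were higher and 3 lower, and 3 and 4 when adjusted over the list alone (set test adjusted p = 0.473). PGGT1B, which encodes the specific subunit of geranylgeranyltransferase I, was not past the threshold (log2 change -0.11, adjusted p = 0.581). It was called lower with the GC trend taken out (-0.23, adjusted p = 0.023) and was at -0.25 (adjusted p = 0.054) with library type terms. With array weights PGGT1B was at 0.05 (adjusted p = 0.773). The Rab escort gene CHML and the methyltransferase gene ICMT fell by 0.55 and 0.47. CHM was higher at 0.53 over all libraries and 0.20 (adjusted p = 0.217) within the first type. Without 1000 nM replicate 2 the adjusted p of CHML was 0.128, and without replicate 3 that of CHM was 0.0823. Of the 24 mevalonate and cholesterol synthesis genes, 3 were higher and 4 lower with a median of 0.05 (adjusted p = 0.938).

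Among the members of the mevalonate list, GGPS1, which encodes geranylgeranyl diphosphate synthase, rose by 0.79. MSMO1, which encodes a sterol oxidase, was at 0.54 over all libraries and was at 0.25 within the first library type (adjusted p = 0.0712). HMGCS1, which encodes an early enzyme of the pathway, was at 0.29 (adjusted p = 0.0847). It passed the threshold without 1000 nM replicate 2 or DMSO replicate 2 (adjusted p = 0.0336 or 0.0315), but not with library type terms alone. With GC trends and type terms together HMGCS1 was at 0.17 (adjusted p = 0.0467). Of the 12 KLF genes, 8 were higher and 1 lower, also when adjusted over the list alone (median 0.79, adjusted p = 4.92e-06, and 6.58e-05 with an estimated correlation). KLF9, KLF7 and KLF3 rose by 1.89, 1.52 and 1.51, and KLF4 was at 0.20 (adjusted p = 0.193), but was called with library type terms (0.27, adjusted p = 0.0396), also with array weights added (0.24, adjusted p = 0.0475). Of the 26 interferon-stimulated genes, 17 were higher and 0 lower, with 18 higher when adjusted over the list alone and a median of 0.47 (adjusted p = 2.79e-05, and 0.000485 with an estimated correlation), led by the oligoadenylate synthase genes OAS2 at 1.23 and OAS1 at 0.99. Of the 21 NRF2 and aryl hydrocarbon receptor targets, 12 were higher and 1 lower, also when adjusted over the list alone (median 0.52, adjusted p = 4.92e-06, and 0.000541 with an estimated correlation), including the aldo-keto reductase genes AKR1C1 at 1.45 and AKR1B10 at 1.38 and CYP1B1 at 1.37.

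Other lists passed at 24 h with the preset correlation but not with an estimated one. Of the 32 lysosome and autophagy genes, 15 were higher and 1 lower, including the regulator TFEB at 1.01 and the autophagosome gene MAP1LC3B at 0.71 (median 0.28, adjusted p = 0.000715, and adjusted p = 0.158 with an estimated correlation). TFEB had an adjusted p of 0.0625 without 1000 nM replicate 2. Of the 9 luminal epithelial markers 6 were higher and 2 lower (median 0.61, adjusted p = 0.212 with an estimated correlation and 0.0603 with a pseudocount of 0.1), among them the mucin gene MUC1 at 1.71 and the keratin gene KRT19 at 1.11. Of the 21 immediate early genes 8 were higher and 2 lower, and 9 and 2 when adjusted over the list alone (median 0.35, adjusted p = 0.581 with an estimated correlation and 0.0912 without the libraries under 2 M reads), with the AP-1 gene FOSL1 at -1.33 and the feedback inhibitor genes SPRY4 at 1.03 and DUSP4 at 1.0. JUND was at 0.99 over all libraries and at 1.22 within the first type, with an adjusted p of 0.0814 there and 0.0795 without 1000 nM replicate 2. Of the 30 glycolysis and hypoxia genes 10 were higher and 3 lower (median 0.13, adjusted p = 0.504 with an estimated correlation), with the stress gene NDRG1 at 1.81 and the vasodilator gene ADM at -1.39.

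The remaining lists did not pass the set test at 24 h, but 3 of them were called higher with library type terms. These were the inhibitor and p53 list (adjusted p = 0.0148), the NF-kB list (0.0294) and the mitochondrially encoded messages (0.0148). The tests with type terms used the preset correlation only. Of the 22 cyclin-dependent kinase inhibitor and p53 target genes 8 were higher and 0 lower (adjusted p = 0.0963), including CDKN1C at 1.53, the proapoptotic gene BBC3 at 1.31 and CDKN1A at 0.96 ± 0.22 (SE; adjusted p = 0.000579). Without 1000 nM replicate 2 the adjusted p of BBC3 was 0.061. Of the 20 NF-kB targets and cytokines 7 were higher and 3 lower (adjusted p = 0.103), with the cytokine gene IL11 at -2.33 and the inhibitor of apoptosis gene BIRC3 at 0.93. Of the 26 unfolded protein and integrated stress response genes 11 were higher and 6 lower (adjusted p = 0.192), and the serine and folate enzyme genes PSAT1, MTHFD2 and SHMT2 fell by 1.43, 1.17 and 0.85. SDF2L1, which encodes a chaperone cofactor, was at -1.23 over all libraries and at 0.01 within the first type, and its adjusted p was 0.676 without 1000 nM replicate 1. Of the 32 extracellular matrix, adhesion and TGF-beta response genes 13 were higher and 8 lower (adjusted p = 0.376), with thrombospondin THBS1 at -1.95, fibronectin FN1 at 1.48 and COL6A1 at 1.30. Of the 16 BCL2 family genes 4 were higher and 2 lower (adjusted p = 0.916), with BCL2 at -0.98, BMF at 0.87 and BCL2L12 at -0.85, the last at -0.20 (adjusted p = 0.567) within the first type and with an adjusted p of 0.382 without 1000 nM replicate 3. Of the 37 nuclear respiratory chain genes 7 were lower and 0 higher (adjusted p = 0.251), including cytochrome c (CYCS) at -0.65, with an adjusted p of 0.095 without 1000 nM replicate 2. Of the 5 fibroblast and pericyte markers 1 was higher (set test adjusted p = 0.916), COL1A2 at 0.60. With array weights COL1A2 was at 0.28 (adjusted p = 0.0785). Its adjusted p was 0.147 with only the groups compared and 0.0526 with the GC trend taken out. Of the 13 mitochondrially encoded messages 1 was higher (set test adjusted p = 0.186), MT-ND3 at 0.38. Its adjusted p was 0.0556 to 0.107 without any 1 of the treated libraries or of DMSO replicates 2 and 5. The list named for nuclear-retained RNAs had 5 members tested (set test adjusted p = 0.869). Of these 1 was higher (LINC00657 at 0.86) and 1 lower (SNHG1 at -1.30), and where in the cell they lie was not measured. The leukocyte, endothelial and basal markers had 2, 3 and 3 members tested and no set test, and LYZ was at 1.38, KDR at -0.47 and the integrin gene ITGB4 at 1.73.

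At 24 h limma called 5506 genes at 1000 nM (3025 higher and 2481 lower), 4864 at 300 nM (2617 and 2247) and 3122 at 100 nM (1662 and 1460), and 825, 659 and 203 of them changed at least 2-fold. The balance of directions depended on the method, since voom called 2328 higher and 2851 lower at 1000 nM, 2508 and 3747 at 300 nM, and 1472 and 1821 at 100 nM, and with median-of-ratios scaling 1512 were higher and 1554 lower at 100 nM. Within the first library type the counts were 5698, 6798 and 5660, and 3881, 4442 and 3089 of the pooled calls were kept. With library type terms they were 7535, 7080 and 4855. At 1000 nM 179 of the 207 genes lower at 6 h were also lower at 24 h, against 32.4 expected if the calls were independent, and 99 of the 112 higher genes were also higher, against 21.4. All 17 genes lower at 3 h were lower at 24 h. On simulated values with the depths of this comparison, in which 200 of 15866 genes changed, 42 of 197 calls were genes without a change and 79.1% of the 2-fold changes were recovered. That share of the calls does not carry over to the 5506 calls, since as many changed genes were not simulated.

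The doses were compared with each other within each time. At 24 h CYR61, CTGF and DKK1 were lower at 1000 nM than at 100 nM by a log2 change of -2.36, -2.11 and -2.07 (SE 0.08 each, adjusted p = 7.89e-27, 1.38e-26 and 1.5e-26). CYR61 averaged 12.2 ± 2.17 FPKM (SD, n = 3) at 1000 nM and 64.5 ± 2.16 FPKM (SD, n = 3) at 100 nM. RHOB was higher by 1.13 (adjusted p = 0.000286), but was not called with only the groups compared (adjusted p = 0.2). The microRNA gene MIR1282 was also past the threshold at 2.27 (adjusted p = 0.0412), and at 0.30 (adjusted p = 0.957) within the first library type. The pseudogene NAMPTP3 averaged 2.74 FPKM at 1000 nM and was listed at 0 in all 3 libraries at 100 nM (adjusted p = 0.00103, and 0.493 within the first type). Of the 40 S phase genes 34 were lower at the higher dose (median -0.77), and of the 22 YAP1/TAZ targets 9 were lower (median -0.32). At 6 h the genes past the threshold were CYR61 at -0.71, CTGF at -0.64 and DKK1 at -0.56 (adjusted p = 6.92e-07, 6.92e-07 and 1.42e-05), and with only the groups compared there were 0. Between these doses limma called 0 genes at 1 h and 0 at 3 h (974 and 615 at an unadjusted p under 0.05), 3 at 6 h and 784 at 24 h (330 higher and 454 lower), and voom called 0, 0, 3 and 552. The count at 24 h was 1256 with library type terms, of which 623 were shared, 825 within the first type, of which 364 were shared, and 3 with only the groups compared. Leaving out any 1 of the 6 libraries moved it by over 1.5 times, to 374, 358 and 429 without 100 nM replicates 1, 2 and 3, and to 354, 2713 and 359 without those of 1000 nM. Without 1000 nM replicate 2 the balance turned to 1450 higher and 1263 lower. Replicates 1 and 3 of 1000 nM were of the second library type, and all 3 libraries of 100 nM were of the first. Dose and library type thus cannot be told apart in the count without replicate 2.

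Whether the effect of 1000 nM differed between times was tested with interaction terms. From 1 to 3 h the effect on CYR61 changed by -1.06 ± 0.10 (SE) on the log2 scale (adjusted p = 1.98e-09), on CD274 by -0.85 and on CTGF by -0.83. Without 1000 nM replicate 3 at 1 h the adjusted p of CD274 was 0.108. From 3 to 6 h the effect on RHOB rose by 1.41 (adjusted p = 0.00159), and on BMF and KLF7 by 0.89 and 0.67. BMF lost its call without 1000 nM replicate 2 at 3 h or replicate 3 at 6 h (adjusted p = 0.127 or 0.107), and KLF7 lost it without any 1 of 13 libraries (0.0519 to 0.176). The effect on ANKRD1, CTGF and the oxytocin receptor gene OXTR fell by 1.28, 1.27 and 1.21 over the same interval. From 6 to 24 h the effect on NOX5 rose by 3.16 and on AGR2 by 2.65, and on PRIM1 it fell by 2.29. All 40 S phase genes had a lower effect at 24 h than at 6 h (median -1.41), as did 30 of the 42 mitosis genes. The numbers of genes past the threshold were 8 (0 higher and 8 lower), 36 (6 and 30) and 2398 (1295 and 1103), and 19, 101 and 4347 with library type terms. From 6 to 24 h voom gave 847 higher and 1480 lower.

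In DMSO alone 2893 genes differed between 24 h and 1 h, with 6 libraries at each time. DDIT4 rose by 2.47 ± 0.17 (SE) on the log2 scale, from 8.27 ± 1.94 FPKM (SD, n = 6) to 47.7 ± 8.05 FPKM (SD, n = 6; adjusted p = 1.19e-15). The interferon-stimulated gene IFIT1 and the transcription factor gene SNAI1 rose by 1.38 and 1.37, and TFF1, which encodes a trefoil peptide, fell by 2.49 (adjusted p = 4.11e-09). The mitochondrial transfer RNA MT-TP and the small nucleolar RNA SNORA66 were at -2.44 and -2.39, and with library type terms at -0.77 and -1.72 (adjusted p = 0.165 and 0.122). Of the 40 S phase genes 30 were lower and 1 higher (median -0.36), while 26 of the 42 mitosis genes were higher and 0 lower (median 0.31). Of the 32 extracellular matrix genes 19 were lower and 0 higher, and of the 26 interferon-stimulated genes 15 were higher and 0 lower. Of the 2 lists of RNA quality, the mitochondrially encoded messages had 4 of 13 lower (median -0.58). The list named for nuclear-retained RNAs had 3 of 5 lower (median -0.79). With library type terms 0 and 1 were lower in these lists. The counts were 1552 higher and 1341 lower, against 1354 and 1477 with median-of-ratios scaling and 1973 and 1121 with voom, with 3953 genes past the threshold with library type terms and 3438 within the first type, of which 2080 were shared. Without the third library type 1304 genes passed, and with only the groups compared 1012. Treated libraries were compared only with DMSO libraries of their own time.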

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

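The test of S phase genes within the first library type, the test with GC trends taken out and the splits with library type terms were chosen after their results, or closely related ones, had been seen. That type terms end the array-weight calls at 1 h was also known, and single pseudogenes had been seen to lose their call in the first type, before these patterns were tested.

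Differences of the 1000 nM effect between times were found by interaction terms. Between 1 and 3 h 8 genes differed, with CYR61 at -1.06, CD274 at -0.85 and CTGF at -0.83. Between 3 and 6 h 36 differed, with RHOB at 1.41, BMF at 0.89, KLF7 at 0.67, ANKRD1 at -1.28, CTGF at -1.27 and OXTR at -1.21. Between 6 and 24 h 2398 differed, with NOX5 at 3.16, the pseudogene HMGA1P5 at 2.79, AGR2 at 2.65, the long non-coding RNA KCNQ5-IT1 at -2.36, PRIM1 at -2.29 and the pseudogene SFTA1P at -2.26. Within the first library type HMGA1P5 was at 1.13 (adjusted p = 0.371) and KCNQ5-IT1 at -1.14 (adjusted p = 0.0571).

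In 8 of 48 tests of single measures in the 4 groups of 6 DMSO libraries, 1 library lay farther from the others than Dixon's critical ratio for 6 samples, where chance flags about 1 in 20 groups. The tests are not independent, since the same libraries recur. In 6 of the 8 the library was of the second type. In DMSO 24 h replicate 2, which had 0.475 M reads, ANKRD1 was at 156 FPKM against 109 to 120 in the others (ratio 0.749) and CDKN1A at 12.9 against 25.1 to 27.9 (ratio 0.816). DMSO 3 h replicate 6 had AMOTL2 at 11.4 against 16.9 to 19.6 FPKM (ratio 0.673) and CDKN1A at 23.2 against 32.8 to 36.3 (ratio 0.735). PGGT1B was at 2.59 FPKM in DMSO 6 h replicate 5 against 1.46 to 1.82 (ratio 0.684), and HMGCS1 at 8.7 in DMSO 1 h replicate 3 against 6.8 to 7.15 (ratio 0.816). The other two were KLF2 in DMSO 6 h replicate 1, of the first type, at 15.0 against 1.92 to 6.13 FPKM (ratio 0.677), and the total reads of DMSO 3 h replicate 1, of the third type, at 48.6 M against 2.37 to 14.3 M (ratio 0.742).

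Array weights called 6032 genes at 1000 nM after 1 h, where 0 passed without weights. Of these genes 98.2% had the sign of the difference between the second and first library types, estimated without any 1 h library. With array weights and type terms together the count was 0. Of the 3 libraries of 1000 nM at 1 h, 2 were of the second type, against 1 of the 6 DMSO libraries. Library type is thus a candidate explanation for these calls.

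The S phase genes fell at 1000 nM after 24 h with a median of -1.45 over all libraries. Within the first library type, where 1000 nM has a single library, the median was -1.46. With GC trends taken out and type terms added over all libraries it was -1.53, with 40 of 40 lower. With reads thinned to 2 M per library in the 57 deep enough libraries, without type terms, it was -1.56, and 40 of 40 were lower. These values argue against library type, GC content and depth as the cause, and a biological decline of S phase transcripts stays a hypothesis from the same data.

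Of 1798 pseudogenes tested, 78 changed at least 2-fold at 1000 nM after 24 h (33 higher and 45 lower). Their median absolute log2 change was 1.25 over all libraries and 0.67 within the first type, a share of 0.53, and 28 were still called there, where 1000 nM has a single library. For 539 protein-coding genes the share was 0.99 and 527 were still called. With type terms over all libraries 68 of the 78 pseudogenes were still called. A single term may not remove the whole difference, since the pseudogene index ran from 2.82 to 5.62 within the second type. Library type thus stays open as an explanation for these pseudogenes. The parent gene was taken from the pseudogene's symbol, without its ending of P and a number, where a gene of that name was tested. Of the 68 with such a parent, 57 (83.8%) had its sign (exact one-sided binomial p = 6.4e-09, with genes that are not independent). Reads shared between parent and pseudogene are thus a candidate explanation.

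Each count of changed genes was compared with other splits of the same libraries into groups of the same sizes. At 1 h the real counts were 0, so all 84 of 84 splits gave as many at each dose by definition, which tests nothing. The highest other counts at 1 h were 6079, 277 and 387 at 1000, 300 and 100 nM. At 3 h the number of splits with as many genes was 7 of 84 at 1000 nM (real 21, highest other 1432), a share that does not exclude chance. It was 2 of 84 at 300 nM (20 and 1256) and 2 of 84 at 100 nM (11 and 1547), each a share under 0.05. Of the 17 genes lower at 1000 nM after 3 h, 16 were also lower at 6 h, against 0.222 expected if the calls were independent. Of the 4 higher genes 3 recurred, against 0.0282. The libraries of these times are separate, so the recurrence argues against chance for the lower genes. At all 3 doses the highest other split at 3 h set the 3 DMSO libraries of the third type apart. With type terms as many genes came from 2, 1 and 1 of the 84 splits at these doses, with real counts of 36, 17 and 13 and highest others of 49, 10 and 1.

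At 6 and 24 h the share of splits with as many genes as the real one was under 0.05 at each dose. Several high counts came from splits that followed library type, so this share alone does not exclude chance. At 6 h the splits with as many genes were 1 of 84 at 1000 nM (319 and 77), 4 of 84 at 300 nM (265 and 3745) and 1 of 84 at 100 nM (137 and 53). The highest other split at 300 nM put 300 nM replicate 1 and DMSO replicate 5, both of the second type, into 1 group, and with type terms the highest other was still 1409 against a real 742. With GC trends also out it was 549 against 1237. At 24 h they were 2 of 84 at 1000 nM (5506 and 6843), 2 of 84 at 300 nM (4864 and 5312) and 2 of 84 at 100 nM (3122 and 3593). The highest other splits joined the second-type libraries at 1000 nM and at 300 nM, and DMSO replicates 1, 2 and 4 at 100 nM. With type terms only 1 of 84 splits reached each real count at 24 h, with 7535, 7080 and 4855 genes against highest others of 5742, 5463 and 4191.

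For 1000 nM against 100 nM the 10 splits are too few for a share under 0.05. The splits with as many genes were 10 of 10 at 1 h (real 0, highest other 4) and 10 of 10 at 3 h (0 and 0), which a real count of 0 fixes in advance. They were 1 of 10 at 6 h (3 and 0) and 1 of 10 at 24 h (784 and 2). For the interactions 100 of 7056 splits were drawn, and as many genes came from 9 from 1 to 3 h (real 8, highest other 4936), so chance was not excluded. They were 4 from 3 to 6 h (36 and 408) and 2 from 6 to 24 h (2398 and 4434), each a share under 0.05. With type terms the first of these was 2 of 100 (19 and 59). For DMSO at 24 h against 1 h, 2 of 100 drawn splits gave as many (2893 and 4080), also a share under 0.05. The highest other exchanged the second-type DMSO 1 h replicate 3 for DMSO 24 h replicate 5. Splits that call several times the real count point to a structure of the samples, which the library types describe in part.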

How the results depend on the processing

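Doses are given in the order 1000, 300 and 100 nM, and the cause of each move was not tested unless stated. A pseudocount of 0.1 and median-of-ratios scaling kept all 20 counts within 1.5 times the reported ones, but scaling turned the balance of directions at 100 nM after 24 h (1512 higher and 1554 lower) and for DMSO over time (1354 and 1477). Without a filter on low values the counts became 21, 9 and 10 at 1 h, 31 (300 nM) and 26 (100 nM) at 3 h, and 490 (1000 nM) and 462 (300 nM) at 6 h. For 1000 against 100 nM they were 22 at 1 h, 9 at 3 h and 9 at 6 h, and 16 for the interaction from 1 to 3 h. With only the groups compared, which leaves fewer samples to estimate the spread, they were 2, 4 and 2 at 3 h, 117, 74 and 49 at 6 h, and 2987, 2695 and 1966 at 24 h. Between 1000 and 100 nM they were 0 at 6 h and 3 at 24 h, for the interactions 2, 22 and 1510, and for DMSO over time 1012.

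With array weights the counts were 6032 (1000 nM) and 1 (100 nM) at 1 h, 1978, 2549 and 3413 at 3 h, 1815, 1762 and 1097 at 6 h, and 9156 (300 nM) and 6226 (100 nM) at 24 h. For 1000 against 100 nM they were 2656, 9, 30 and 5711 at 1, 3, 6 and 24 h, for the interactions 3629, 1870 and 6042, and for DMSO over time 4710.

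All following alternatives were chosen after the data had been seen. Array weights with library type terms gave 38 (300 nM) at 1 h, 46, 43 and 32 at 3 h, 2103, 2326 and 1223 at 6 h, and 9045 (300 nM) and 6361 (100 nM) at 24 h. Between 1000 and 100 nM they gave 32 at 6 h and 2678 at 24 h, for the interactions 391 from 3 to 6 h and 5479 from 6 to 24 h, and for DMSO over time 4940. Library type terms alone gave 1 (100 nM) at 1 h, 36 (1000 nM) at 3 h, 738, 742 and 345 at 6 h and 4855 (100 nM) at 24 h. For 1000 against 100 nM they gave 6 at 6 h and 1256 at 24 h, and for the interactions 19, 101 and 4347. The first library type alone gave 6 (100 nM) at 3 h, 1222, 767 and 535 at 6 h, 5660 (100 nM) at 24 h, 10 for 1000 against 100 nM at 6 h, and 213 and 3674 for the interactions from 3 to 6 h and from 6 to 24 h. Without the third type the counts were 9 (300 nM) and 3 (100 nM) at 3 h, 3 for the interaction from 1 to 3 h and 1304 for DMSO over time.

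With each GC trend taken out the counts were 53 (1000 nM) and 21 (100 nM) at 3 h, 767, 655 and 348 at 6 h, and 1, 8 and 1675 for 1000 against 100 nM at 1, 6 and 24 h. The interactions gave 16, 140 and 3737. GC trends and type terms together gave 1 (100 nM) at 1 h, 62 (1000 nM) and 18 (100 nM) at 3 h, 1169, 1237 and 603 at 6 h and 5238 (100 nM) at 24 h. Between 1000 and 100 nM they gave 5, 11 and 1753 at 1, 6 and 24 h, for the interactions 30, 194 and 4624, and for DMSO over time 4360. With voom on the recovered reads the counts were 21 at 3 h and 256 at 6 h for 100 nM. Without the 3 libraries under 2 M reads the counts were 1 (1000 nM) at 1 h, 405 (300 nM) at 6 h, 1485 for 1000 against 100 nM at 24 h and 15 for the interaction from 1 to 3 h.

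Leaving out 1 library at a time gave ranges at 1, 3, 6 and 24 h of 0 to 4, 13 to 34, 173 to 313 and 4399 to 5903 for 1000 nM. They were 0 to 1, 10 to 23, 165 to 311 and 4048 to 4848 for 300 nM, and 0 to 4, 6 to 16, 65 to 131 and 2061 to 3217 for 100 nM. For 1000 against 100 nM they were 0 to 1, 0 to 5, 3 to 3 and 354 to 2713, for the interactions 5 to 12, 21 to 48 and 1838 to 3054, and for DMSO over time 2239 to 3737. At 1 h the count was 4 without 1000 nM replicate 1, 1 without its replicate 2, 1 without DMSO replicate 1 (300 nM), 4 without 100 nM replicate 1 and 2 without its replicate 2. At 3 h it was 34, 13 and 34 without 1000 nM replicates 1, 2 and 3, 13, 10 and 13 without those of 300 nM, and 7 and 6 without 100 nM replicates 2 and 3. At 6 h it was 189, 188 and 173 without each of the 1000 nM replicates, 165 without 300 nM replicate 1, and 75, 65 and 80 without those of 100 nM. At 24 h it was 2061 without 100 nM replicate 1. Between 1000 and 100 nM it was 1 at 1 h without 100 nM replicate 1, 3 and 5 at 3 h without 1000 nM replicates 1 and 3, and at 24 h 374, 358 and 429 without those of 100 nM and 354, 2713 and 359 without those of 1000 nM. The interaction counts moved this far without 1000 nM replicate 3 at 1 h (5) and replicate 1 at 6 h (21).

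Of 288 set tests 108 passed, and 51 of these passed with an estimated correlation. The settings that follow used the preset correlation. A pseudocount of 0.1 kept 107 and scaling kept 108. Type terms called 113, kept 82 and turned 4 to the other direction, all of them the mitochondrially encoded messages, at 1 h at each dose and at 3 h at 100 nM. The first type alone called 105, kept 77 and turned 5, and GC trends with type terms called 116, kept 81 and turned 4. Without the libraries under 2 M reads 110 were called and 103 kept. For the 191 values of named genes, 4092 of 4324 alternative values kept their direction and side of the threshold, 221 lost the call, 9 gained it and 2 changed sign. Of the gained calls 6 were for HMGCS1, 2 for KLF4 and 1 for PGGT1B, all at 1000 nM after 24 h. The changes of sign were SDF2L1 at 24 h, at 0.01 in the first library type, and PGGT1B, at 0.05 with array weights, and the cause was not tested. Of the lost calls 86 came from leaving out a library, 39 from using only the groups compared and 23 from the first type alone. Only the groups compared left without a call, among others, ANKRD1, CD274, EDN1, AMOTL2, FAM46C, BTG1 and TSC22D1 at 1000 nM after 3 h, KLF2 after 6 h, and CDKN1C, BBC3, TFEB, COL6A1, CYCS, KDR and COL1A2 after 24 h, with the same log2 changes. Array weights did so for JUND (0.69, adjusted p = 0.0626), KDR (-0.29, 0.0751), MT-ND3 (0.31, 0.141) and COL1A2 after 24 h.

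No paired analysis was possible because the labels number the samples from 1 to 60 and share no replicate number between groups. Depth limits the calls at 1000 nM after 24 h, where libraries had 2.27 to 31.8 M reads. Changed genes were simulated in this group only. The simulated share of false calls was 21.3% at these depths with limma on log2 FPKM, 7.7% with voom, and 3.6% with the former at equal depths. These shares hold for 200 changed genes of 15866 and were not simulated for more. In 17 simulated comparisons without change limma made 4 calls and voom made 10 at the real depths. The simulated values held no library types.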

Other observations

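The tests in this part were chosen after the named genes and the list results at 3 and 6 h had been seen, so the MYC and FOXO tests are not independent of them. The MYC gene, which encodes a growth-promoting transcription factor, is outside the rule for named genes. At 1000 nM its log2 change was -0.14 at 1 h (adjusted p = 0.515), -0.67 at 3 h (8.52e-05), -0.85 at 6 h (5e-08) and -0.81 at 24 h (7.01e-09), with a standard error of 0.10. At 300 nM MYC fell by 0.50 at 3 h and by 0.96 at 6 h, and at 100 nM by 0.55 at 6 h, while its value at 100 nM after 3 h was -0.41 (adjusted p = 0.187). At 1000 nM the ribosome biogenesis and MYC target list was first past its set test downward at 6 h over all libraries. With the preset correlation it passed downward already at 3 h within the first library type (adjusted p = 0.035). With GC trends and type terms together it also did so (0.0453). Lower MYC mRNA stays open as a candidate explanation for that list, since a fall of MYC to -0.85 in the same libraries does not show that it acts on these genes, and no protein was measured.

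Several genes higher at 3 and 6 h, such as BTG1, CCNG2, KLF9 and TSC22D3, are known targets of FOXO transcription factors. A list of 15 other FOXO targets was written before its values were seen, of which SESN1 and CDKN1B also belong to the list of cell cycle inhibitors and p53 targets. At 1000 nM after 6 h its median was 0.12 and camera gave p = 0.000318 upward, and 0.000386 with an estimated correlation. Of the 15 genes 11 were above 0, 3 were higher past the threshold and 0 lower. The 3 were the stress sensor gene SESN3 at 0.50, the thioredoxin inhibitor gene TXNIP at 0.37 and PDK4, which encodes a pyruvate dehydrogenase kinase, at 0.60. With library type terms 4 were higher and 1 lower. The insulin receptor substrate gene IRS2 moved the other way at -0.65 (adjusted p = 0.0531). These values are consistent with FOXO-driven transcription as a hypothesis, and with other regulators of the same genes that were not tested.

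The slope of expression on GC content, in log2 per 10 GC points, was -0.234 to 0.362 in the first library type (median 0.074), -0.461 to -0.097 in the second (median -0.286) and 0.009 to 0.213 in the third (median 0.138). Within the first type DMSO 6 h replicate 1 (0.362) and DMSO 24 h replicate 4 (-0.234) had the highest and the lowest slope. The median FPKM of the nuclear RNA MALAT1 was 10.7 in the third type and 1.49 in the first. The share of mitochondrial reads was 1.02 to 2.01% in the first type, 0.979 to 1.84% in the second and 2.82 to 3.31% in the third. The labels name no feature that separates the types.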
